A study of Homo sapiens with 4 samples.

How the data were processed

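Single cells from 2 high-grade serous ovarian tumours were profiled with a droplet method that tags each cell's RNA with a cell barcode and each RNA molecule with a unique molecular identifier (UMI). Per the labels' protocols, each tumour was separated by flow cytometry into CD45-positive cells, which are leukocytes, and CD45-negative cells, and each fraction became a library of its own, giving 4 libraries, 1 per tumour and gate. The labels' protocols state a target of 10000 recovered cells per sample, 13 cycles of cDNA amplification, a 16-base cell barcode and a 10-base UMI. They name a 3′ reagent kit (the prime sign is garbled) and, in the same sentence, 5′ chemistry versions.

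The deposited tables used here are a list of cell barcodes and a table of features, both for the whole series. Neither holds a measured level, and the UMI counts behind them were not analysed here, so no expression value, cell type share or fold change is given. Per the submitters' processing notes, Cell Ranger 3.1.0, Seurat 4.0.1 and the human genome build GRCh38 were used; which step each served, the gene annotation release and the rule that separated cells from empty droplets are not given in the sources used here. The file naming describes the barcode list as filtered. Each entry of the list deposited by the authors is a 16-base sequence followed by a suffix from 1 to 4. The sources used here do not tie a suffix to a tumour or gate, so the 4 suffixes are called library parts, entered no comparison between groups, and are given by suffix number. The labels also do not say which tumour is the high-stromal one.

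No doublet caller was run, since it needs UMI counts, and whether the authors removed doublets is not given in the sources used here. Barcodes were counted per suffix, and each part's share of all barcodes was given a 95% exact (Clopper-Pearson) binomial interval, which covers counting error only. Sequences present in both parts of a pair were counted for the 6 pairs. The expected number was the product of both parts' sizes divided by the size of the pool from which barcodes are drawn. The pool was set, before the data were examined, to 737280, the size of the barcode list that the maker of the droplet system uses for 5′ kits and older 3′ kits, called the smaller bead set below. This size is background knowledge and the list itself was not used here. Each pair was tested with a two-sided exact hypergeometric test, with Benjamini-Hochberg adjustment over the 6 pairs; the pairs share libraries, so the 6 tests are not fully independent. The summed number was set against 2000 random draws of 4 parts of the same sizes. A pool size was also estimated by capture and recapture, as the summed products of sizes divided by the summed shared barcodes, with an exact Poisson interval. Each barcode was further divided into positions 1 to 7 and positions 8 to 16, counted from the 5′ end, a division chosen after the data were seen, and the numbers of distinct words were estimated with the bias-corrected Chao1 estimator. The second word was permuted among the barcodes of each part 10000 times. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

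The pair test and the pool estimate were tested on simulated data, with 200 draws per pool and parts of the real sizes. For the smaller bead set, the interval held the true pool in 96% of draws and 0.583% of pair tests passed an adjusted p of 0.05. For a pool of 3500000, the interval held the true pool in 95.5% of draws and 100% of pair tests passed.

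Features were matched by Ensembl gene identifier, without version, to GENCODE release 44, whose build is GRCh38; coordinates are from that release, 1-based, because the feature table gives none. Of 33538 features, 33113 (98.7%) matched. Marker lists for 16 cell types or states were fixed before the data were examined, and their 64 genes are the genes named, only for whether and how the feature table holds them. Overlap was counted between annotated exons of a marker and of any other matched feature. The alternatives were barcodes found in 1 part only, removal of barcodes 1 base from another, a pool estimated from the other pairs, identity allowing 1 mismatch, and marker matching that ignored case. Pools of 3500000 and of the product of word numbers were added after the data were seen. The alternatives that need UMI counts were not run.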

Results

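The study set a high-stromal against a low-stromal ovarian tumour and, within each, CD45-positive leukocytes against CD45-negative cells, which include the tumour epithelium and the stroma. The labels describe 4 libraries, 1 per tumour and gate, so neither comparison has replicates. The data analysed here are the barcodes called as cells and the genes against which their RNA was counted. They give the number of barcodes called as cells per library part and the genes that could be measured, and no expression level.

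In all, 23408 cell barcodes were listed under 4 suffixes. Suffix 3 held the most, with 7332 barcodes or 31.3% of the total (95% exact binomial interval 30.7% to 31.9%). Suffix 4 held 6684 barcodes, or 28.6% (interval 28.0% to 29.1%). Suffix 1 held 5126 barcodes, or 21.9% (interval 21.4% to 22.4%), and suffix 2 held 4266, or 18.2% (interval 17.7% to 18.7%). The intervals do not overlap, but they cover counting error only and say nothing about a tumour or a gate, since no suffix was tied to either. The largest part was 1.72 times the smallest, and the parts reached 42.7% to 73.3% of the stated target of 10000 cells. UMI depth per cell is unknown here, and doublets, barcodes that hold more than 1 cell, could not be assessed from the barcode list and were not removed, so a barcode count is not exactly a cell count.

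Markers of the cell types that the CD45-positive and CD45-negative fractions could hold, from lists not taken from the study, were all present in the feature table. The feature table holds the genes that could be counted, so presence there says nothing about whether a marker's RNA was found in these cells. Of 64 genes in the 16 cell type lists, 63 matched exactly 1 feature and 1 matched 2 features, so 15 of the 16 lists were matched without ambiguity. PTPRC (ENSG00000081237), which encodes CD45 and so is the transcript of the sorted protein, lies on chromosome 1 from 198638457 to 198757476 on the plus strand. None of its annotated exons overlapped an exon of another matched feature. All 8 epithelial tumour genes were present. They include EPCAM, an epithelial adhesion molecule, on chromosome 2 from 47345158 to 47387601, and PAX8, a transcription factor of the Müllerian lineage, on chromosome 2 from 113215997 to 113278921. They also include MUC16, which carries the CA125 antigen, on chromosome 19 from 8848844 to 9010390.

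For the stroma, all 7 fibroblast genes and all 4 myofibroblast genes were present. COL1A1, a chain of type I collagen, lies on chromosome 17 from 50184101 to 50201632 on the minus strand. DCN and LUM, which encode small proteoglycans of the matrix, lie near each other on chromosome 12, at 91140484 to 91183217 and 91102629 to 91111494. FAP, a surface protease of activated fibroblasts, lies on chromosome 2 from 162170684 to 162245151. The table held 44 collagen alpha chain genes by symbol. All 4 endothelial genes (PECAM1, VWF, CDH5 and CLDN5) and all 4 mesothelial genes (MSLN, CALB2, LRRN4 and UPK3B) were present.

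The exception was RGS5, a regulator of G protein signalling used as a pericyte marker. Its symbol named 2 features, the protein-coding gene ENSG00000143248 on chromosome 1 from 163111121 to 163321791 and the long non-coding gene ENSG00000232995 from 163244505 to 163321894. Both lie on the minus strand and their exons overlap, so a value looked up by the symbol RGS5 could belong to either. RGS5 was one of 24 symbols that were listed for 2 features each. The other 4 pericyte and smooth muscle genes (MCAM, PDGFRB, MYH11 and DES) matched once.

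Of the 65 features that carry a marker symbol, 49 had no exon overlap with another matched feature. Overlap on the same strand occurred for 3, the pair named RGS5 and PDGFRA, a fibroblast receptor that shares exon sequence with ENSG00000282278. Overlap on the opposite strand occurred for 14. ACTA2, the smooth muscle actin of myofibroblasts, overlapped FAS and ACTA2-AS1, and TAGLN, an actin-binding protein, overlapped PCSK7. KRT8 and KRT18, which encode epithelial keratins, overlapped each other. How such reads were assigned is not given in the sources used here.

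For leukocytes, every T cell, NK cell, B cell, plasma cell, macrophage and monocyte, dendritic cell and mast cell gene in the lists was present once. The table also held 214 immunoglobulin and 195 T cell receptor gene segments, the loci rearranged in B and T cells. Protein-coding genes made up 19656 of the matched features (59.4%) and long non-coding RNA genes 12717 (38.4%). Pseudogenes numbered 314 of the 15233 in the annotation. They included 187 of 187 in the class IG_V_pseudogene but 1 of 10146 in the class processed_pseudogene. None of the annotation's 7030 genes in the classes miRNA, snRNA, snoRNA, scaRNA, rRNA and misc_RNA was listed. These numbers describe the gene set used for counting and not the cells. The 13 features with the mitochondrial prefix were present, so a mitochondrial share per cell could be computed from the counts.

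Some barcodes occurred in more than 1 library part. Over the 6 pairs of parts, 54 sequences were shared, and 0 occurred in 3 or more parts. If every part had drawn its barcodes at random from the smaller bead set of about 740000 sequences, 275 shared sequences would be expected, and 2000 simulated draws gave 222 to 325. The observed number was 0.197 of that expectation (95% exact Poisson interval 0.148 to 0.257). Each pair fell below its expectation, with 6 to 15 shared sequences against 29.7 to 66.5 expected, and the adjusted p of the exact hypergeometric test was between 2.79e-13 and 2.54e-07. With a pool of 3500000 sequences, a setting chosen after the data were seen, observed over expected was 0.715 to 1.07 and 0 of the 6 pairs passed the threshold (each adjusted p of 1 by the exact test). The test compares these library parts and not the tumours or gates.

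**Figure D1:**
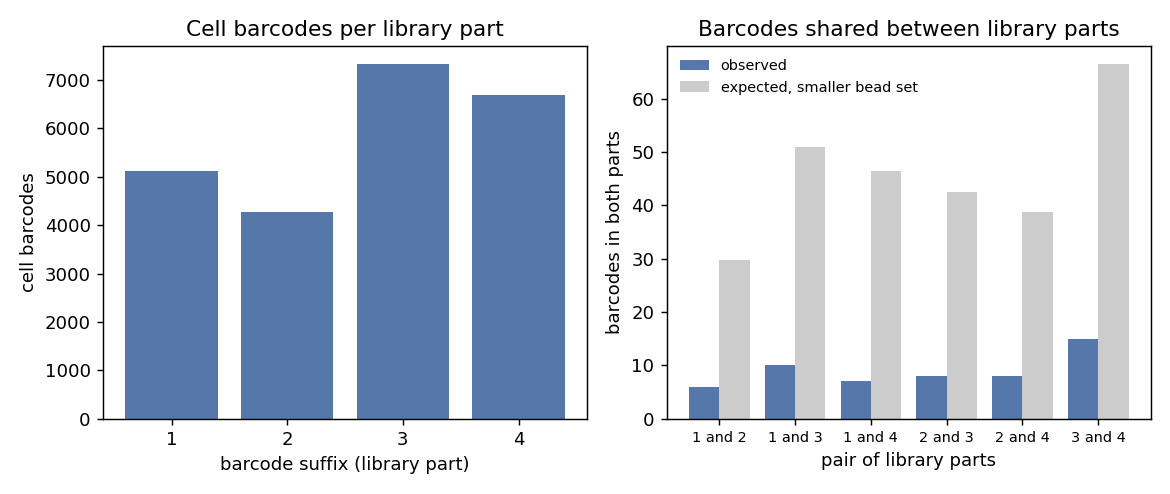
Left, the number of cell barcodes (vertical axis) listed under each barcode suffix (horizontal axis), from 4266 for suffix 2 to 7332 for suffix 3. Right, for each of the 6 pairs of suffixes (horizontal axis), the number of barcode sequences found in both parts (blue) beside the number expected for random draws from the smaller bead set (grey); the blue bar is lower in every pair.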

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

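The number of barcodes per suffix hardly moved: keeping those found in 1 part only left 5103, 4244, 7299 and 6654 for suffixes 1 to 4, and removing barcodes 1 base from another took 2 from suffix 4 and none from the others. The marker count stayed at 63 when case was ignored. Allowing 1 mismatch between parts left the shared count of every pair as it was, so no further barcode matched at 1 base. That setting says nothing about the size of the pool. The shortfall of shared barcodes depends on the assumed pool. The pool estimated from the other pairs is computed from these same shared barcodes, so ratios near its expectation follow largely by construction. That setting tests only whether a pair differs from the rest, and not whether the shortfall against the smaller bead set is real. With the pool estimated from the other pairs, observed over expected became 1.033 for suffixes 1 and 2, 0.9973 for 1 and 3, 0.7314 for 1 and 4, 0.9521 for 2 and 3, 1.061 for 2 and 4, and 1.205 for 3 and 4. With the pool from the product of word numbers, in the same order, it was 0.9898, 0.9599, 0.737, 0.9227, 1.012 and 1.104. With a pool of 3500000 it was 0.9603, 0.9313, 0.7151, 0.8952, 0.982 and 1.071. No pair passed the threshold under these 3 pools (exact hypergeometric test, each adjusted p of 1); the last 2 were chosen after the data were seen. By construction a larger pool lowers the expectation. With 6 to 15 shared sequences per pair, a modest departure in a single pair was not detectable. The alternatives that need UMI counts were not run.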

Other observations

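The tests in this part were chosen after the shared barcodes had been counted. The pattern is that the 4 library parts shared 54 barcodes where the smaller bead set, named for 5′ kits, would give 275. A candidate explanation is a larger bead set. The first 7 bases took 960 distinct words and the last 9 took 3745 (Chao1 estimate 3758), a product of 3610000, and permuting the last 9 bases among the barcodes of each part gave a mean of 56.0 shared barcodes (central 95% of permutations 42 to 71) against the observed 54 (two-sided permutation p = 0.846). The cut was placed after 7 bases because distinct prefixes numbered 960 at both 6 and 7 bases and 3829 at 8. The product and the permutation hold for this cut only, and no permutation was run for other cuts. Capture and recapture gave 3750000 (95% interval 2870000 to 4990000), which restates the 54 shared barcodes as a pool size and is not separate evidence. Removal of part of the shared barcodes before deposit, together with a restricted set of word pairings, was not tested and stays open. Carry-over of barcodes between libraries would add shared barcodes and so does not account for a shortfall. No excess was seen against the permuted range either. That range, 42 to 71, assumes free pairing of the words, and a small carry-over within it would not be seen. No biological explanation was tested.

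The permutation shows no departure from free pairing of the words and does not test which kit was used. As a hypothesis only, these barcodes may come from a bead set larger than that of the 5′ chemistry that the labels also name. With the product of word numbers as the pool, observed over expected was 0.737 to 1.104 over the 6 pairs. The product is counted without reference to the shared barcodes, but it assumes, as the permutation does, that the words pair freely. It gave 56.1 expected shared barcodes against the permuted mean of 56.0, so it is not separate evidence from the permutation. The comparison with the product was chosen after the data were seen, and the barcode lists of the kits were not used here. The labels' UMI length of 10 bases goes with the 5′ kits and older 3′ kits, so it is open which statement holds.

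At positions 8 and 9 of the barcode, only 4 of the 16 possible dinucleotides occurred: TC in 26.0% of barcodes, CA in 25.9%, AG in 24.4% and GT in 23.7%.

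Of the features matched by identifier, 10545 (31.8%) had a gene name in GENCODE release 44 that differed from the deposited symbol. For some genes that name is the identifier itself, as for ENSG00000232995, deposited as RGS5. How many of the 10545 are of this kind was not counted, so 31.8% is not a share of renamed genes. Of the deposited symbols that differed, 10532 were not a gene name in that release and 13 named another gene there. By identifier, 425 of the 33538 features found no match.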
